A study of Homo sapiens with 21 samples.

How the data were processed

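Gene-level expression arrays measured RNA in 21 samples of cells labelled GM12878: total input RNA, a negative control RIP with an antibody against a bacteriophage coat protein, and RIPs of ELAVL1, PABPC1, CELF1, SLBP and IGF2BP1, 3 arrays each. The arrays' number limits the precision. Array signal was summarised by the authors with PLIER, per the submitters' processing notes (version not given in the sources used here), and the deposited values are log2 of the PLIER estimate plus 16, with no value below 4. The values were not equalised between arrays. The deposited region lists, 1 per group and attached to its first replicate, give transcript regions on hg19. In these lists the authors gave a score from 0 to 1000 computed from the p, a fold of at least 2 whose denominator is not given in the sources used here, and a p-value with a q-value, with no p-value of 0.05 or more. A second version, as deposited, holds the -log10 of the same p and q. The list attached to the negative control sample holds a signal level per region, which the deposited values show to be the geometric mean of the 3 total input arrays. The test and control arrays behind the authors' lists are not given in the sources used here.

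Of 28869 features, 19310 had exactly 1 gene symbol, 1752 several and 7807 none, and features with 1 symbol stood for 18377 genes. All features were tested. The deposited log2 values were fitted without further normalization with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with 1 mean per group over all 21 arrays. Each RBP RIP was compared with the negative control RIP, with total input and with the mean of the other 4 RBP RIPs, and the negative control RIP with total input. A feature was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. The array batches were read from the day code in the array names.

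In 20 gene lists fixed from general knowledge, shifts were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison, and counts of called members were adjusted over all features and over the list alone. The lists were replication-dependent and polyadenylated histones, reported targets of ELAVL1, CELF1 and IGF2BP1, ribosomal protein genes, other TOP mRNAs, respiratory chain, glycolysis, proteasome and mitotic genes, small nucleolar RNAs, small structured RNAs, nuclear noncoding RNAs, zinc-finger genes, NF-kappaB response genes, B-cell identity genes, T-cell, myeloid and erythroid genes, olfactory receptor genes, and mitochondrially encoded mRNAs, of which 0 were measured. Named genes had exactly 1 symbol, with the feature of highest mean standing for a gene. Against the negative control they were the 10 largest rises and 5 largest falls among called features whose groups did not overlap and whose higher mean lay above the median of all features. Against the other RBPs and for the negative control against total input they were the 5 largest each way, and against total input the 3 largest each way. The mRNAs of the immunoprecipitated proteins and up to 2 members at each end of a list were added.

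Overlaps between RBPs were set beside independent lists and beside 100 simulations without differences on shared controls. Region lists were intersected with bedtools 2.31.1 at 1 base. Tables and figures used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9, and correlations within batches statmod 1.5.0. The procedure was tested on simulated data with 1 spread per feature shared by all groups and 50 changed features per size. The real groups differed in spread, with a median SD of 0.83 in the negative control RIP and 0.28 in SLBP RIP. The recovery given here therefore holds for equal spreads. Of 50 features changed by 0.5 on the log2 scale 0 were recovered, by 1 0 to 1, by 2 14 to 23 and by 3 41 to 44, depending on the comparison, with 1 to 6 false calls and 0 of wrong sign. A list shift of 1 was recovered as 0.85 to 1.12, and 0 of 18 other lists were called. The simulated features were drawn independently of each other, while the real mitotic list, for example, had an estimated correlation of 0.76. The simulation therefore gives no rate of false calls for correlated lists. Alternatives were quantile normalization, centring on array medians, a filter on dim features, features with 1 symbol only, other variance models, the replicate number or array batch as a block, fits within a batch, and leaving out each replicate. The reference genome sequence was not used here.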

Results

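RNA that co-purified with 5 RNA-binding proteins (RBPs) was measured on gene-level expression arrays in cells labelled GM12878, a B-lymphoblastoid line. In RNA immunoprecipitation (RIP), antibody-coated beads take a protein and the RNA bound to it out of a cell lysate. ELAVL1 (HuR) binds AU-rich elements, PABPC1 binds poly(A) tails and CELF1 binds GU-rich elements. SLBP binds the stem-loop that ends histone mRNAs, and IGF2BP1 is a fetal mRNA-binding protein that tumours often express again. The controls were total input RNA and a negative control RIP with an antibody against a bacteriophage coat protein. The 21 arrays formed 7 groups of 3, each replicate being a separate RIP run per the series design, and their number limits the precision. Values were on the log2 scale for 28869 features, with a floor of 4.

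The signal of whole arrays differed between the groups. Array medians averaged 9.04 ± 0.18 (SD, n = 3) in PABPC1 RIP and 7.94 ± 0.12 in SLBP RIP, against 6.08 ± 0.081 in the negative control RIP and 6.03 ± 0.18 in total input. ELAVL1 RIP (6.87 ± 0.11), the arrays labelled IGF2BP1 (6.67 ± 0.048) and CELF1 RIP (6.35 ± 0.045) lay between them. Every PABPC1 and SLBP array lay above every control array, which is the smallest p, 0.1, that an exact permutation test of 3 against 3 arrays can give. The deposited values were not equalised between arrays, so changes of lists are given relative to the median of all features. The labels placed the arrays in 7 batches. A RIP shared a batch with control arrays for CELF1 (all 3 arrays, with negative control replicates 2 and 3 and total input replicate 1), PABPC1 replicates 1 and 2 (total input replicate 2), SLBP and IGF2BP1 (total input replicate 3) and ELAVL1 replicate 1 (negative control replicate 1). No negative control array shared a batch with PABPC1, SLBP or IGF2BP1. A fit with the batch as a fixed block compares them with that control through total input. The last step there is total input replicate 1 against negative control replicates 2 and 3. ELAVL1 replicates 2 and 3 were alone in their batches, so that fit compares ELAVL1 replicate 1 with negative control replicate 1.

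**Figure D1:**
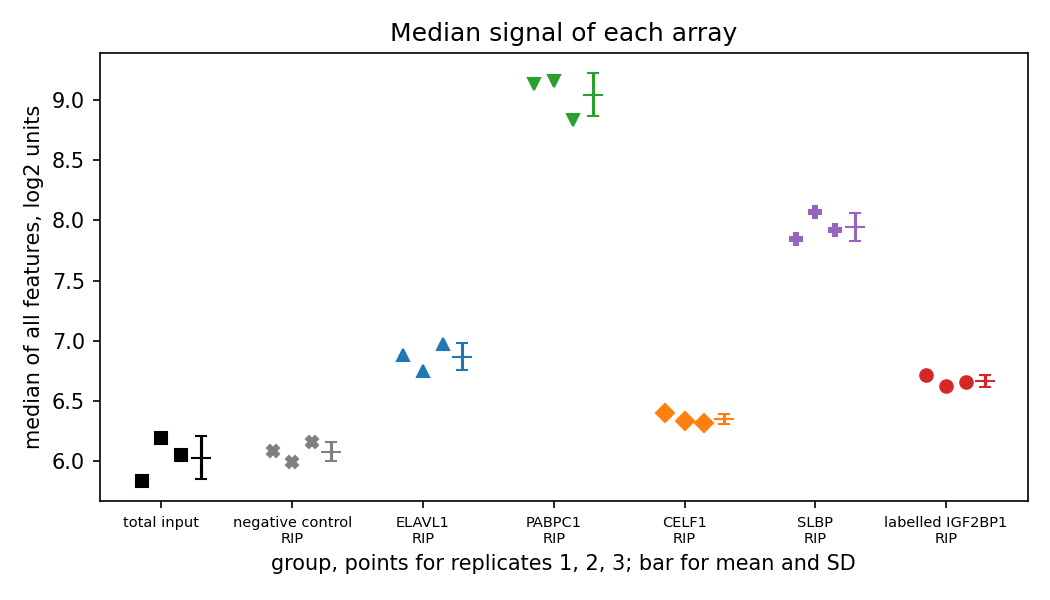
Median log2 value of all 28869 features on each array (points, replicates 1 to 3) by group, with the group mean and SD as bars. The PABPC1 RIP arrays lay between 8.84 and 9.16 and the negative control arrays between 5.99 and 6.16.

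Embryonic globin transcripts separated some arrays from the rest. HBZ and HBE1 encode embryonic globins, GATA1 encodes the transcription factor of red-cell precursors and ALAS2 encodes the first enzyme of heme synthesis in those cells. HBZ, HBE1 and ALAS2 were higher on the 3 arrays labelled IGF2BP1 and on negative control replicate 3 than on average in any other group of RIPs or in total input. JCHAIN and MS4A1 (CD20), genes of the B lineage, were low on the same arrays. HBZ averaged 13.15 on the arrays labelled IGF2BP1 and measured 13.65 on negative control replicate 3, against 5.53 and 5.58 on negative control replicates 1 and 2. GATA1 was 11.16 and 8.32 on the same arrays, against 4.15 on replicate 1 and the floor of 4 on replicate 2. In PABPC1 RIP, whose arrays were the brightest, GATA1 averaged 8.76, above negative control replicate 3, and HBZ 8.80, and HBZ averaged 8.62 in SLBP RIP. JCHAIN averaged 5.18 on the arrays labelled IGF2BP1 and between 10.62 and 12.84 in the other 4 RIPs of RBPs. HBE1 and JCHAIN differed between the arrays labelled IGF2BP1 and the mean of the other 4 RBP RIPs (limma adjusted p 8.5e-05 and 1.15e-05).

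A list of erythroid marker genes, written after the correlations between arrays had been seen, had 18 measured members. Its median relative to the array median was 3.83 to 4.01 on the arrays labelled IGF2BP1 and 3.12 on negative control replicate 3. On the other 17 arrays it lay between -1.98 and 1.07. The median of 25 B-lineage markers lay between -0.04 and 0.10 on the arrays labelled IGF2BP1, -1.73 on negative control replicate 3, 0.011 on replicate 2 and -1.06 on total input replicate 1. The other 15 arrays lay between 1.88 and 3.74. Negative control replicate 2 and total input replicate 1 also had 15.3% and 16.6% of features within 0.2 of the floor. Across features, which are not independent replicates, negative control replicate 3 correlated best with a replicate labelled IGF2BP1 (r = 0.822). The negative control arrays correlated with each other at r = 0.345 to 0.746, and the CELF1 RIP arrays at 0.935 to 0.949. PABPC1 replicates 1 and 2 reached r = 0.994. Comparisons are therefore also given without negative control replicates 2 and 3 and total input replicate 1, an alternative chosen after these values were seen. This alternative leaves 1 negative control array, replicate 1. Its effect sizes carry no measure of the spread between controls, and any p-value under it borrows the spread of the other groups.

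**Figure D2:**
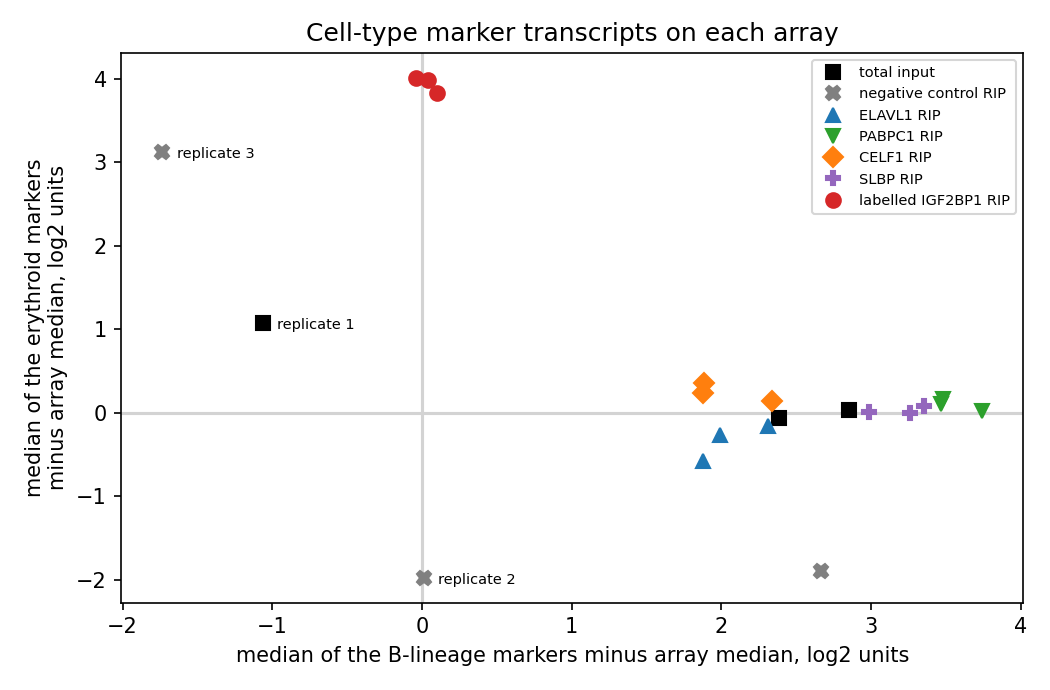
Each point is 1 array: the median of 25 B-lineage markers (horizontal) and of 18 erythroid markers (vertical), each minus the array median, in log2 units, coloured by group. The 3 arrays labelled IGF2BP1 and negative control replicate 3 lay above the other 17 arrays, whose highest erythroid median was 1.07.

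Each RBP RIP was compared with the negative control RIP to ask which transcripts were recovered above the background of the procedure. In ELAVL1 RIP, CCL3, which encodes a chemokine, TNFAIP3, which encodes a brake on NF-kappaB signalling, and the mRNA of ELAVL1 itself were higher. CXCR4, a chemokine receptor of lymphocytes, and CPEB3, a regulator of translation, were also higher. HMOX1, which encodes a heme-degrading enzyme and is on the list of reported ELAVL1 targets, was lower. RPS9, a ribosomal protein gene, was lower too. SGCB, which encodes a membrane protein of muscle, had the largest fall.

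Of the 28869 features, 8230 were higher and 1427 lower in ELAVL1 RIP (limma, adjusted p under 0.05), and the median log2 fold change of all features was 0.67. With each array centred on its median the split was 2968 higher and 3829 lower, and with quantile normalization 3566 and 3958. The arrays of the groups were fully separated for 28.4% of features, where chance gives 10%. AKR1E2, an aldo-keto reductase gene (feature 7925904, chromosome 10, 4868402 to 4890254, hg19), averaged 11.56 ± 0.31 (SD, n = 3) against 4.58 ± 1, a log2 fold change of 6.99 (limma adjusted p 4.21e-09). Its negative control mean, here and in the other comparisons, lay near the floor of 4, so the size of the rise is uncertain. IFIT5, CBFB, CHMP1B, CDC42SE2, FOXN3, PLAC8, PPP3R1, CPEB3 and CXCR4 followed with 5.42 to 5.87. SGCB, DGAT2L6, COL27A1, NWD2 and ACOT7 were lower, with log2 fold changes from -5.70 to -4.60. ELAVL1 mRNA averaged 11.47 ± 0.60 against 6.77 ± 1.66 (log2 fold change 4.70, limma adjusted p 0.00016). CCL3 and TNFAIP3 were higher by 4.99 and 3.88, and HMOX1 and RPS9 fell by 1.80 and 1.33.

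Among 38 reported AU-rich mRNAs bound by ELAVL1, 25 were higher and 1 lower over all features, and 28 and 1 adjusted over the list alone. Their median lay 1.07 above that of all features (camera adjusted p 0.000577). NF-kappaB response genes (0.91, adjusted p 0.0231), B-cell identity genes (1.16, 0.0261) and zinc-finger genes (0.51, 0.033) also lay above it, and ribosomal protein genes below it (-0.51, 0.0231). With an estimated correlation between genes, the adjusted p of these 5 lists was 0.803 to 0.898, so none held. POU2AF1, a B-cell coactivator gene, was higher by 4.30 with all arrays, and was 8.49, 5.44 and 4.02 on negative control replicates 1 to 3. Without the 3 arrays that stood apart, 1 negative control array remained. The AU-rich list then lay at 0.90, the NF-kappaB list at -0.34 and the B-cell list at -0.53. The median log2 fold change of all features was then 0.67. With the array batch as a fixed block, the NF-kappaB and B-cell lists reversed to -0.16 and -0.41. The other ELAVL1 arrays were alone in their batches, so these values are those of ELAVL1 replicate 1 minus negative control replicate 1. Leaving out 1 array at a time gave between 846 without negative control replicate 2 and 2718 without negative control replicate 3 for the lower count. Within the batch that held ELAVL1 replicate 1 and negative control replicate 1, the fold changes correlated across features with those of all arrays at r = 0.779, and 1 array against 1 allowed no test.

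In ELAVL1 RIP, the calls of RPS9, TNFAIP3 and the zinc-finger list ended with the array batch as a fixed block, which compares 1 array with 1. Other calls ended when 1 array was left out (adjusted p in parentheses). HMOX1 (0.073), and the ribosomal protein (0.0523) and zinc-finger (0.16) lists lost the call without ELAVL1 replicate 2. HMOX1 (0.088) lost the call without negative control replicate 1. The B-cell (0.529), NF-kappaB (0.468), ribosomal protein (0.89) and zinc-finger (0.0693) lists lost the call without negative control replicate 3.

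**Figure D3:**
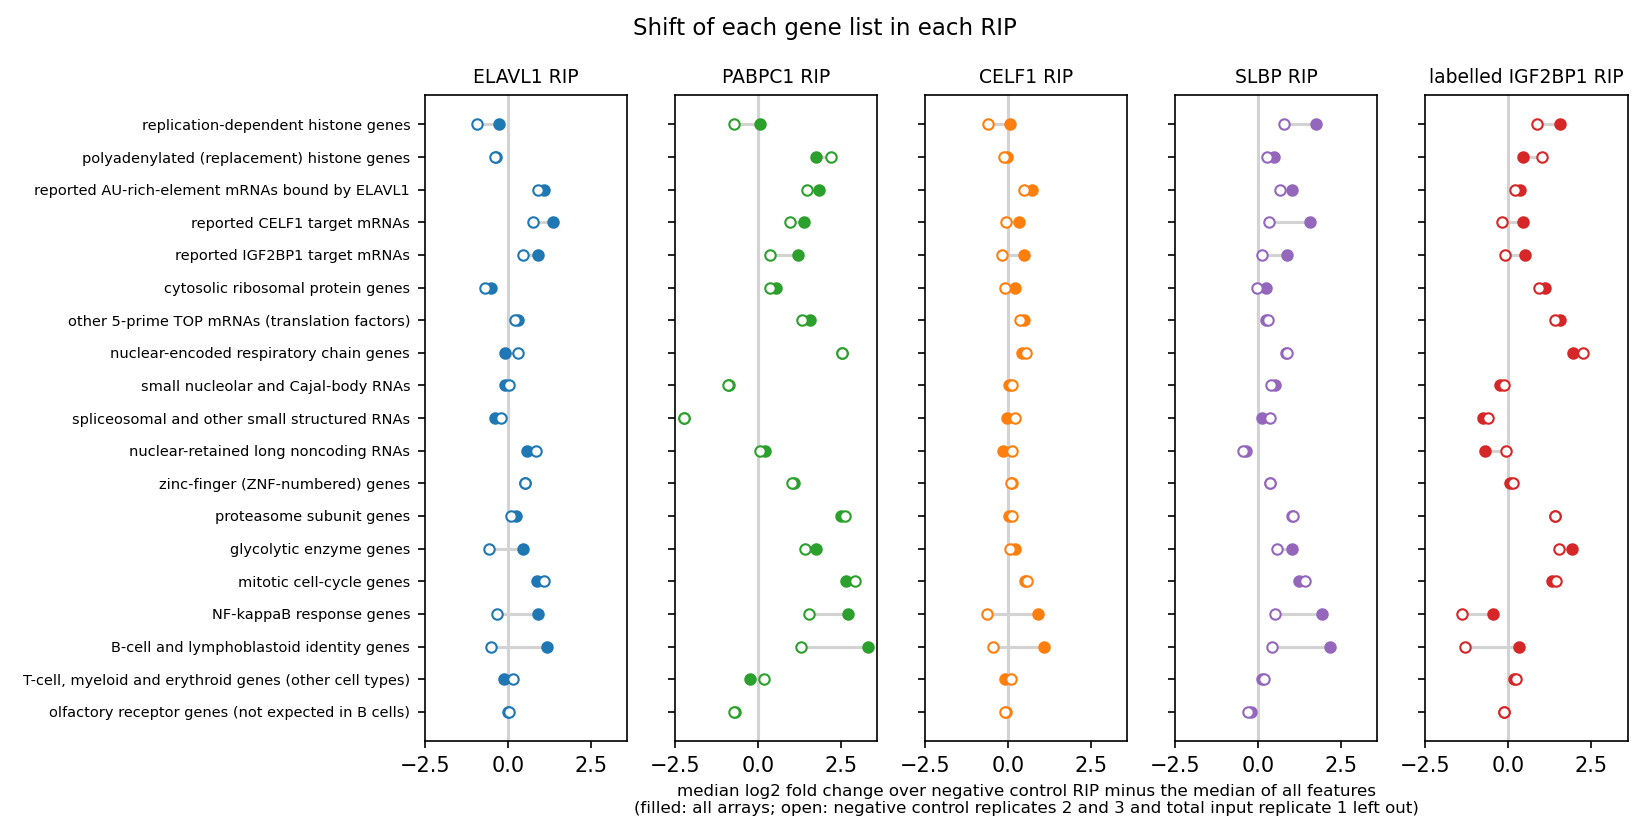
Median log2 fold change of each fixed gene list against the negative control RIP minus the median of all features, in log2 units, 1 panel per RBP. Filled points use all arrays and open points leave out negative control replicates 2 and 3 and total input replicate 1, which moved the B-cell list in ELAVL1 RIP from 1.16 to -0.53. The open points rest on 1 negative control array.

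In PABPC1 RIP most features were higher than in the negative control before the arrays were centred, so the lists are given against the shift of all features. RMRP and RPPH1 are the RNA subunits of RNase MRP and RNase P and are made without a poly(A) tail, and both were lower. NDUFA9 encodes a subunit of the respiratory chain, PSMD6 a subunit of the proteasome and CCNB1 the mitotic cyclin B1, and these mRNAs were higher. SNORD49A, a small nucleolar RNA that guides RNA methylation, was also higher, although its class rose less than the median feature. PAX5, the transcription factor of B-cell identity, and CD27, a receptor of lymphocytes, had large rises. PAX5 was 8.84 on negative control replicate 1 and 4.01 and 4.33 on replicates 2 and 3, which enlarged its rise.

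In PABPC1 RIP, 23992 features were higher and 216 lower than in the negative control (limma), with a median log2 fold change of 2.40. With each array centred on its median the split was 7351 higher and 11542 lower, and quantile normalization gave 5473 and 5987. The groups were separated for 79.4% of features (10% by chance). PLAC8, a gene of lymphoid and myeloid cells, averaged 12.88 ± 0.14 (SD, n = 3) against 5.19 ± 1.81 (log2 fold change 7.69, limma adjusted p 1.25e-08). CD27, SKAP1, MX2, ABI3, NPC2, RRAGD, IAH1, CYP1B1 and HLA-DPB1 followed with 7.22 to 7.52. CDH5, EDA, MSRB3, PPP1R14C and CCNJ were lower (-4.07 to -3.05). RMRP averaged 9.09 ± 0.42 against 11.51 ± 0.76 (-2.42, adjusted p 0.00335), and RPPH1 fell by 2.11 (adjusted p 0.0373). NDUFA9, PSMD6, CCNB1, PAX5 and SNORD49A were higher by 6.46, 6.39, 5.85, 7.04 and 5.47. PABPC1 mRNA averaged 14.20 ± 0.09 against 10.25 ± 2.41 (log2 fold change 3.95, adjusted p 2.15e-05), a call that ended with each array centred on its median (adjusted p 0.185).

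Small structured RNAs such as RMRP lay -2.23 relative to all features in PABPC1 RIP, with 7 of 22 members higher and 3 lower (6 and 2 adjusted over the list alone; camera adjusted p 3.17e-13). This call held with an estimated correlation (adjusted p 0.00489), but not with the 3 arrays that stood apart left out as well. That fit has 1 negative control array, and the list lay at -2.23 in it. Small nucleolar RNAs lay -0.89 relative to all features, although 139 of 188 were higher (camera adjusted p 6.67e-05). Above the median feature lay mRNAs of the respiratory chain (2.52, adjusted p 0.000111), the proteasome (2.48, 0.00106), mitotic genes (2.65, 0.0154), zinc-finger genes (1.07, 0.000115), AU-rich mRNAs (1.84, 0.00312), NF-kappaB response genes (2.71, 0.00312) and B-cell identity genes (3.31, 0.00159). Histone genes had a relative median of 0.043 while camera placed them below the other features (adjusted p 0.0306). The adjusted p with an estimated correlation of the lists other than the small structured RNAs was 0.594 to 0.768. Without the 3 arrays that stood apart, against 1 negative control array, the NF-kappaB list lay at 1.52 and the B-cell list at 1.28. Olfactory receptor genes, which B cells are not known to express, had a median log2 fold change of 1.72, with 294 of 339 higher and OR2H1 lower (-2.74). The array batch as a fixed block gave 15475 higher and 226 lower features and turned the direction of the respiratory, proteasome and mitotic tests, whose relative medians were then 0.64, 0.31 and 0.52. Histone, HLA, globin, zinc-finger and small nucleolar RNA families share near-identical sequences, so their features can include signal from paralogs.

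In PABPC1 RIP, calls that ended with the array batch as a fixed block (adjusted p in parentheses) were those of CCNB1 (0.111), PSMD6 (0.123), and the NF-kappaB (0.106), AU-rich (0.421) and zinc-finger (0.0642) lists. RPPH1 lost the call without PABPC1 replicate 3 (0.152) or negative control replicate 2 (0.136) or 3 (0.057). The mitosis list did without PABPC1 replicate 3 (0.0741) or negative control replicate 2 (0.125). The histone list did without negative control replicate 1 (0.189) or 3 (0.982), and the NF-kappaB list without replicate 3 (0.053).

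CELF1 destabilises short-lived mRNAs with GU-rich elements. JUN, an immediate early transcription factor gene, and TNFRSF1B, which encodes a receptor of tumour necrosis factor, were higher in CELF1 RIP than in the negative control. MYOD1, the muscle transcription factor gene, and HMOX1 were lower. FGF2, which encodes a growth factor, STAR, which encodes a cholesterol carrier, and PARP12, which encodes an interferon-induced enzyme, were among the largest rises. The reported CELF1 targets as a list, and the mRNA of CELF1 itself, did not pass the test.

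In CELF1 RIP, 1600 features were higher and 594 lower than in the negative control (limma), with a median log2 fold change of 0.095. The share of higher features moved when arrays were centred on their median (1237 higher, 838 lower). The groups were separated for 13.8% of features (10% by chance). AKR1E2 averaged 12.03 ± 0.06 (SD, n = 3) against 4.58 ± 1 (log2 fold change 7.45, limma adjusted p 1.22e-09). ALDH6A1, KLHL11, PARP12, CYTH3, TCFL5, STAR, FGF2, TPRG1L and BLTP3B followed with 5.43 to 6.37, and SGCB, HIF3A, EDA, TRMT61A and VAMP5 were lower (-6.54 to -5.24). TNFRSF1B averaged 9.04 ± 0.37 against 5.52 ± 1.42 (3.52, adjusted p 0.000103). JUN was higher by 3.49 and MYOD1 fell by 1.92. HMOX1 fell by 2.81. BCL2 was higher by 2.74 (adjusted p 0.0244). CELF1 mRNA averaged 8.46 ± 0.27 against 7.36 ± 1.47 (log2 fold change 1.10, adjusted p 0.383).

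Of 13 reported CELF1 targets, 3 were higher and 1 lower, both over all features and adjusted over the list alone, and the relative median was 0.33 (camera adjusted p 0.353). AU-rich mRNAs (0.72, adjusted p 0.00496), NF-kappaB response genes (0.89, 0.0182) and B-cell identity genes (1.07, 0.00208) lay above the median feature, and each had an adjusted p of 0.986 with an estimated correlation. MS4A1 and TNFAIP2, from the B-cell and NF-kappaB lists, were higher by 3.34 and 2.30. MS4A1 averaged 9.46, against 8.91 on negative control replicate 1. Without the 3 arrays that stood apart, 1 negative control array of another batch remained. The B-cell list then lay at -0.46, the NF-kappaB list at -0.63 and the AU-rich list, no longer called, at 0.49. Within the batch that held all 3 CELF1 arrays and negative control replicates 2 and 3, 159 features were higher and 59 lower. The array batch as a fixed block gave 2082 and 588. Leaving out 1 array gave at least 1079 higher (without CELF1 replicate 1) and 364 lower (without CELF1 replicate 3). The highest counts, both without negative control replicate 3, were 4305 and 1560.

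In CELF1 RIP, calls of these genes and lists ended when 1 array was left out (adjusted p in parentheses). BCL2 (0.0545), MS4A1 (0.0651), MYOD1 (0.114) and TNFAIP2 (0.0966) lost the call without CELF1 replicate 1. BCL2 (0.0943) and MS4A1 (0.0538) lost the call without CELF1 replicate 2. BCL2 (0.0832), MS4A1 (0.0735), MYOD1 (0.126), TNFAIP2 (0.0952), and the NF-kappaB (0.073) list lost the call without CELF1 replicate 3. MYOD1 (0.0886) lost the call without negative control replicate 1. BCL2 (0.0663), MS4A1 (0.101), MYOD1 (0.117), TNFAIP2 (0.154), and the AU-rich (0.101) list lost the call without negative control replicate 2. BCL2 (0.0683), and the B-cell (0.549) and NF-kappaB (0.767) lists lost the call without negative control replicate 3.

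SLBP binds and processes the mRNAs of replication-dependent histones, which end in a stem-loop in place of a poly(A) tail. H2BC14 and H3C3, genes of histones H2B and H3, were higher in SLBP RIP than in the negative control. SNORD41 and SNORD116-15, small nucleolar RNAs, were higher as well. MS4A1 and CCR7, surface receptor genes of B cells, and NFKB2, a subunit of NF-kappaB, were also higher. MS4A1 and CCR7 were 8.91 and 8.75 on negative control replicate 1 and 4.39 to 5.07 on replicates 2 and 3, which enlarged their rises. Most other features were higher too, so histones are given against the shift of all features.

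In SLBP RIP, 19140 features were higher and 343 lower than in the negative control (limma), with a median log2 fold change of 1.55. Centring each array on its median gave 2430 higher and 6028 lower, and quantile normalization 3141 and 3513. The groups were separated for 63.9% of features (10% by chance). AKR1E2 averaged 12.16 ± 0.12 (SD, n = 3) against 4.58 ± 1 (log2 fold change 7.58, limma adjusted p 8.8e-10). TMEM192, H2BC14, MS4A1, ZNF74, GAB3, SNORD41, CCR7, CENPB and SP110 followed with 5.74 to 6.39, and ZNF618, LCA5, PTGDS, SMARCA1 and KCNJ10 were lower (-4.30 to -3.76). H2BC14 averaged 12.79 ± 0.11 against 6.49 ± 3.54 (6.30, adjusted p 0.000374). H3C3, SNORD116-15 and NFKB2 were higher by 5.13, 5.30 and 4.68. SLBP mRNA averaged 10.31 ± 0.20 against 7.19 ± 2.41 (log2 fold change 3.12, adjusted p 0.00315), and the call ended with each array centred on its median (adjusted p 0.223).

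Of 51 replication-dependent histone genes, 44 were higher in SLBP RIP over all features and 46 adjusted over the list alone, and none was lower. Their median lay 1.73 above all features (camera adjusted p 0.014). Polyadenylated histone genes had a relative median of 0.48 (adjusted p 0.8). Small nucleolar RNAs (0.52, adjusted p 0.000268), AU-rich mRNAs (1.01, 0.0277), NF-kappaB response genes (1.93, 0.014) and B-cell identity genes (2.17, 0.000886) also lay above the median feature. With an estimated correlation the adjusted p of these lists was 0.906. Olfactory receptor genes had a median log2 fold change of 1.33, with 248 of 339 higher. Without the 3 arrays that stood apart, against 1 negative control array, the histone list lay 0.77 above all features. The calls of the B-cell list (0.42) and the NF-kappaB list (0.50) ended without those arrays. With the array batch as a fixed block, 7331 features were higher and 316 lower. The histone list was then at -0.029, the polyadenylated histones at -0.94, the AU-rich list at -0.41 and the NF-kappaB list at -0.69. Relative to total input in the same batch, the histone list lay 0.16 above all features in SLBP RIP and 0.51 above them on the arrays labelled IGF2BP1.

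In SLBP RIP, calls that ended with the array batch as a fixed block (adjusted p in parentheses) were those of H3C3 (0.16), KCNJ10 (0.0664), NFKB2 (0.0549), SLBP (0.914), SMARCA1 (0.117), and the B-cell (0.414) list. The histone (0.487) and AU-rich (0.233) lists lost the call without negative control replicate 2. The B-cell (0.0543) and NF-kappaB (0.292) lists lost the call without negative control replicate 3.

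On the arrays labelled IGF2BP1, transcripts of red-cell precursors were higher than in the negative control RIP: HBE1 and HBB encode globins and ALAS2 encodes a heme-synthesis enzyme. KRT18, an epithelial keratin gene, DLK1, a gene of fetal tissues, and UCA1, a noncoding RNA of cancer cells, were higher too. NDUFS8 of the respiratory chain, RPL32 of the ribosome and CDC20 of mitosis were higher, while MALAT1, a nuclear noncoding RNA, and RNU4-1, a spliceosomal RNA, were lower. CTNNB1, which encodes beta-catenin and is a reported IGF2BP1 target, was higher, but the list of reported targets did not pass the test.

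Against the negative control, 5537 features were higher and 807 lower on the arrays labelled IGF2BP1 (limma), with a median log2 fold change of 0.28. Centring each array on its median gave 3456 and 2080, and quantile normalization 3241 and 1869. The groups were separated for 25.9% of features (10% by chance). HBE1 averaged 13.47 ± 0.04 (SD, n = 3) against 6.92 ± 5.05 (log2 fold change 6.55, limma adjusted p 0.00117), a negative control mean that rests on replicate 3. KRT18 averaged 12.65 ± 0.06 against 6.46 ± 1.14 (6.19, adjusted p 4.41e-08). DLK1, ALAS2, CD151, ZNF74, UCA1, CALML4, TMEM54 and KLHL11 ranged, with KRT18, from 5.86 to 6.36. SGCB, HECTD2, ZNF302, KCNC2 and MEI1 were lower (-6.53 to -4.83), as were MALAT1 (-2.39) and RNU4-1 (-2.62). HBB, NDUFS8, H4C13, CDC20, RPL32 and CTNNB1 were higher by 4.54, 5.17, 5.30, 5.39, 3.30 and 2.79. IGF2BP1 mRNA averaged 9.48 ± 0.24 against 7.28 ± 4.03 (log2 fold change 2.20, adjusted p 0.182). Without negative control replicate 3 its log2 fold change was 4.53 (adjusted p 3.28e-08), while without replicate 2 it was 1.03, the lowest of the values with 1 array left out, and was not called.

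Of 14 reported IGF2BP1 targets, 4 were higher over all features and 5 adjusted over the list alone, and the relative median was 0.50 (camera adjusted p 0.201). Lists above the median feature were those of the respiratory chain (1.95, adjusted p 1.24e-08), glycolysis (1.93, 0.000594), the proteasome (1.41, 0.00483), mitosis (1.31, 0.0185), ribosomal proteins (1.11, 0.000262), translation factors with TOP mRNAs (1.55, 0.044) and replication-dependent histones (1.56, 9.39e-05). Small nucleolar RNAs (-0.25, adjusted p 0.0057), small structured RNAs (-0.75, 9.78e-05) and 3 nuclear noncoding RNAs (-0.71, 0.044) lay below it. With an estimated correlation the adjusted p of these lists was 0.309 to 0.695. B-cell identity genes (0.33, adjusted p 0.709), NF-kappaB response genes (-0.46, 0.201) and the list of T-cell, myeloid and erythroid genes (0.18, 0.239) were not called. Without the 3 arrays that stood apart, against 1 negative control array, the B-cell list lay at -1.31 and the NF-kappaB list at -1.38. With the array batch as a fixed block, 1322 features were higher and 1002 lower. The lists of the respiratory chain (-0.70), glycolysis (-1.07), the proteasome (-1.19), mitosis (-1.68), ribosomal proteins (-0.49), TOP mRNAs (-1.26) and histones (-0.26) then reversed. That fit reached the negative control only through the 3 arrays that stood apart. Relative to the 1 total input array of the same batch, all of these lists lay above all features, from 0.33 (TOP mRNAs) to 1.24 (respiratory chain).

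On the arrays labelled IGF2BP1, calls that ended with the array batch as a fixed block (adjusted p in parentheses) were those of ALAS2 (0.0702), CD151 (0.169), CDC20 (0.315), CTNNB1 (0.688), HBE1 (0.171), RPL32 (0.121), UCA1 (0.0616), and the nuclear noncoding RNA (0.0552) list. The TOP mRNA list lost the call without IGF2BP1 replicate 1 (0.0553) or 3 (0.0509) or negative control replicate 1 (0.0573). The nuclear noncoding RNA (0.0789) list lost it without IGF2BP1 replicate 2. The ribosomal protein (0.173), glycolysis (0.0655), mitosis (0.755), nuclear noncoding RNA (0.0655), TOP mRNA (0.58) and proteasome (0.453) lists lost the call without negative control replicate 2. The nuclear noncoding RNA (0.135) and small nucleolar RNA (0.0618) lists lost the call without negative control replicate 3. The B-cell list was called higher without negative control replicate 1 (1.10), and the NF-kappaB list lower without replicate 3 (-0.78).

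The negative control RIP was compared with total input to ask which transcripts the procedure itself recovers or loses. CYRIA, which encodes a regulator of actin, ZBTB39, a zinc-finger gene, STIM2, which encodes a calcium sensor, and CDK19, a kinase gene of the Mediator complex, were higher in the negative control. AKR1E2, SIRT1, which encodes a deacetylase, AP4E1, which encodes an adaptor protein of vesicles, and SRSF8, a splicing factor gene, were lower. RP9P, a pseudogene, was higher. In all, 476 features were higher and 821 lower (limma), and the groups were separated for 6.48% of features, under the 10% that chance gives. RP9P averaged 10.88 ± 0.34 (SD, n = 3) against 5.37 ± 0.58 (log2 fold change 5.51, adjusted p 5.7e-09), and CYRIA, ZBTB39, CDK19 and STIM2 were higher by 4.99 to 5.75. AKR1E2 averaged 4.58 ± 1 against 12.24 ± 0.11 (-7.66, adjusted p 7.07e-10), and KLHL11, SIRT1, AP4E1 and SRSF8 were lower (-7.11 to -6.46). None of the 19 gene lists with measured members was called, at camera adjusted p of 0.287 or more. Without the 3 arrays that stood apart, TOP mRNAs lay at -0.65 and respiratory genes at -0.37, with 1 negative control array against total input. Within the batch that held negative control replicates 2 and 3 and total input replicate 1, limma called 0 higher and 0 lower features, with 2988 at an unadjusted p under 0.05. The array batch as a fixed block gave 2052 higher and 872 lower features, and leaving out 1 array gave between 315 without negative control replicate 1 and 1127 without negative control replicate 3 for the higher count.

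Each RBP RIP was also compared with total input, to ask which RNAs a RIP enriched or depleted relative to the cell. FOXN3, a forkhead transcription factor gene, was higher in ELAVL1 RIP than in total input, as it was against the negative control. SNORD41 was higher and ZNF618 was lower in SLBP RIP against both controls. AKR1E2, the largest rise in 3 RIPs over the negative control, was lower in PABPC1 RIP than in total input. HBE1, HBZ and MPP1, a gene of the red-cell membrane, were higher on the arrays labelled IGF2BP1. Over all features limma called 11197 differences for ELAVL1 RIP, 24432 for PABPC1 RIP, 1784 for CELF1 RIP, 20309 for SLBP RIP and 6906 for the arrays labelled IGF2BP1. The share of higher features among these was 85.0%, 98.8%, 71.0%, 98.1% and 87.4%, and with each array centred on its median 44.8%, 40.6%, 53.5%, 30.3% and 60.8%. With quantile normalization it was 47.0%, 49.4%, 55.8%, 46.1% and 57.4%.

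In log2 fold change over total input, the largest rises in ELAVL1 RIP were SEPTIN7P13 (5.69), FOXN3 (5.42) and TMEM167A (5.38), and the largest falls PRKAA2 (-6.22), MPC1L (-5.42) and COMMD7 (-5.27). In PABPC1 RIP they were LAMP5 (7.31), TDP2 (7.28) and SNX9 (7.14), and AKR1E2 (-5.10), CDH5 (-4.62) and DNAH11 (-4.03). CELF1 RIP had ALDH6A1 (6.40), RP9P (5.87) and ZBTB39 (5.82) higher, and AP4E1 (-6.38), MTNR1A (-6.28) and MPC1L (-5.97) lower. SLBP RIP had SNORD13P3 (5.99), HMGN5 (5.89) and SNORD41 (5.81) higher, and DNAH11 (-5.01), SKIL (-4.79) and ZNF618 (-4.70) lower. The arrays labelled IGF2BP1 had HBE1 (8.11), MPP1 (7.42) and HBZ (6.64) higher, and AP4E1 (-6.22), SGCB (-5.86) and DCDC2 (-5.82) lower. Each of these genes had a limma adjusted p of 0.000809 or less. Within batches, limma called 26421 differences for PABPC1, 504 for CELF1, 24216 for SLBP and 11320 for the arrays labelled IGF2BP1, each against 1 input array, which is assumed to vary like the RIP arrays. With the array batch as a fixed block the counts were 3351, 22199, 6049, 17081 and 3403, in the order ELAVL1, PABPC1, CELF1, SLBP and IGF2BP1. Leaving out 1 array moved the CELF1 count between 1124 without CELF1 replicate 2 and 2218 without total input replicate 3.

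Comparing each RBP RIP with the mean of the other 4 asked which transcripts set that protein apart, without the negative control. SNORD41, SNORD34, SNORD116-14 and SNORD116-15, small nucleolar RNAs, were higher in SLBP RIP than in the others. MIR15A and MIR181A2, microRNA genes, and KRT4, a keratin gene, were higher in ELAVL1 RIP, and NFE2, an erythroid transcription factor gene, was lower. In PABPC1 RIP, CETN2 of the centrosome and PSMB9 of the immunoproteasome were higher, and CDH5, an endothelial cadherin gene, was lower. COL27A1, a collagen gene, and ABCC11, a transporter gene, were higher in CELF1 RIP. IFITM3, an antiviral gene, and the globin genes HBE1 and HBZ were higher on the arrays labelled IGF2BP1, where JCHAIN, HLA-DQA1 and CYTIP, genes of lymphoid cells, were lower.

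Against the other RBP RIPs, limma called 1204 higher and 7840 lower features in ELAVL1 RIP, 23803 and 200 in PABPC1 RIP, 713 and 18525 in CELF1 RIP, 6513 and 430 in SLBP RIP, and 1358 and 11724 on the arrays labelled IGF2BP1. Without the arrays labelled IGF2BP1, 634 were higher in ELAVL1 RIP and 2843 in SLBP RIP. The median log2 fold changes of all features were -0.50, 1.80, -1.18, 0.57 and -0.71. Centring each array on its median gave 3363 higher and 2719 lower for ELAVL1, 5260 and 9112 for PABPC1, 4783 and 2762 for CELF1, 1000 and 1501 for SLBP, and 4553 and 3185 for the arrays labelled IGF2BP1. The share of higher features was 13.3%, 99.2%, 3.71%, 93.8% and 10.4% with all features as deposited and 50.3%, 44.9%, 58.3%, 56.8% and 49.9% after quantile normalization, in the same order. In log2 fold change, SEPTIN7P13 (4.14), SNORD56B (2.52), MIR15A (2.31), MIR181A2 (2.29) and KRT4 (2.16) were the highest in ELAVL1 RIP, although KRT4 reversed to -0.13 with the array batch as a fixed block. PRKAA2 (-5.27), CMYA5 (-4.93), NFE2 (-4.52), CLDN23 (-4.45) and C1orf115 (-4.36) were the lowest. In PABPC1 RIP the ends were CETN2 (5.59), LY86 (5.47), FAHD1 (5.45), TGM5 (5.45) and PSMB9 (5.39), and CDH5 (-3.69), MSRB3 (-3.02), PPP1R14C (-2.98), RPS6KA6 (-2.40) and KCNJ4 (-1.79). CELF1 RIP had ABCC11 (3.20), COL27A1 (3.03), ALDH6A1 (2.79), ABCA11P (2.78) and ZNF833P (2.65) higher, and TRMT61A (-5.35), MTNR1A (-4.93), TGM2 (-4.76), VAMP5 (-4.73) and RPL13AP17 (-4.67) lower.

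SNORD41 averaged 10.66 ± 0.17 (SD, n = 3) in SLBP RIP against a mean of 5.89 in the other RBP RIPs (log2 fold change 4.77, limma adjusted p 1.81e-07). SGCB (4.68), SNORD34 (4.59), SNORD116-15 (4.52) and SNORD116-14 (4.23) followed it, and ZNF618 (-4.35), KCNH2 (-4.06), CRIP2 (-3.73), KCNS2 (-3.29) and TSPAN7 (-3.18) were lower. Of 188 small nucleolar RNAs, 122 were higher in SLBP RIP and 0 lower, with a median 0.85 above all features (camera adjusted p 7.25e-19, and 0.0469 with an estimated correlation). Histone genes lay 1.10 above all features and small structured RNAs 1.02, both at a camera adjusted p of 7.94e-05, and respiratory genes -0.33 relative to them (7.94e-05). With an estimated correlation the adjusted p of these 3 lists was 0.153 to 0.955. On the arrays labelled IGF2BP1, JCHAIN averaged 5.18 ± 0.18 against 11.70 in the other RBP RIPs (-6.52, limma adjusted p 1.15e-05). CYTIP (-6.36), GPR15 (-5.95), HLA-DQA1 (-5.94) and IFI44L (-5.70) were also lower, and HBE1 (6.65), HBZ (5.40), MPP1 (5.32), IFITM3 (5.17) and ALAS2 (4.82) were higher. B-cell identity genes lay -2.12 relative to all features (24 of 34 lower, camera adjusted p 5.78e-05) and NF-kappaB response genes -1.99 (2.6e-05). Histone genes (1.04, 1.35e-07), respiratory genes (0.86, 3.12e-07) and the list of T-cell, myeloid and erythroid genes (0.24, 0.035) lay above them. Under an estimated correlation the adjusted p of these 5 lists was 0.51.

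Small structured RNAs, which lack poly(A) tails, lay -1.84 relative to all features in PABPC1 RIP against the other RBP RIPs (camera adjusted p 1.87e-16), a call that held with an estimated correlation (adjusted p 0.00172). Small nucleolar RNAs (-0.99, adjusted p 1.5e-14) and histone genes (-0.72, 1.81e-09) also lay below all features, and respiratory (1.65, 0.000155) and proteasome genes (1.78, 0.000303) above. Under an estimated correlation the adjusted p of these 4 lists was 0.0621 to 0.838. In ELAVL1 RIP, ribosomal protein (-1.03, adjusted p 4.96e-06), respiratory (-1.24, 8.22e-06) and proteasome genes (-1.05, 0.00131) lay below all features, and AU-rich mRNAs (0.29, 0.0427) and 3 nuclear noncoding RNAs (1.24, 0.0152) above, with adjusted p of 0.198 to 0.746 under an estimated correlation. In CELF1 RIP the small structured RNAs lay 0.92 above all features (adjusted p 5.51e-05, and 0.198 with an estimated correlation), and the reported CELF1 targets were not called (-0.48, adjusted p 0.912). With the array batch as a fixed block, the higher counts were 348, 11829, 810, 1894 and 418 for ELAVL1, PABPC1, CELF1, SLBP and the arrays labelled IGF2BP1. Under that block the respiratory (0.38) and proteasome lists (0.50) of ELAVL1 RIP, the respiratory list of the arrays labelled IGF2BP1 (-0.43) and the reported CELF1 targets (1.24) reversed. For the following RIPs, leaving out 1 array gave the largest higher count without ELAVL1 replicate 1. It was 6587 for SLBP, 815 for CELF1, 1219 for ELAVL1 and 1414 for the arrays labelled IGF2BP1. The smallest were 2358 without SLBP replicate 2, 429 without CELF1 replicate 1, 625 without ELAVL1 replicate 2 and 813 without IGF2BP1 replicate 1.

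For ELAVL1 RIP against the other RBPs, calls that ended with the array batch as a fixed block (adjusted p in parentheses) were those of MIR15A (0.657), MIR181A2 (0.518), NFE2 (0.463), SNORD56B (0.223), and the ribosomal protein (0.957) list. The AU-rich (0.0521) list lost the call without ELAVL1 replicate 3. With the same fixed block, the calls that ended for PABPC1 RIP were those of KCNJ4 (0.225), and the respiratory (0.582) and proteasome (0.139) lists. For SLBP RIP they were those of KCNH2 (0.102) and the histone (0.972) list. For the arrays labelled IGF2BP1 they were those of HBZ (0.157), MPP1 (0.231) and the histone (0.728) list. There the T-cell, myeloid and erythroid list lost the call without ELAVL1 replicate 2 (0.0588), IGF2BP1 replicate 2 (0.0696) or PABPC1 replicate 3 (0.0527).

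The transcripts higher than in the negative control were compared between RBPs, to ask how far different RIPs recovered the same RNAs. ZNF74, a zinc-finger gene, AKR1E2, CYTH3, which encodes an exchange factor for ARF proteins, KLHL11, which encodes a ubiquitin ligase adaptor, and GAB3, which encodes a docking protein, had the largest mean rise among features higher in all 5 RIPs. They were chosen after their values were seen. Their means in the negative control RIP were 4.58 to 6.15, and in total input 10.58 to 12.24, so the negative control was low for all of them. Over all features, 772 were higher in all 5 RIPs, where independent lists would share 48.2. In simulations in which no feature differed and the 3 control arrays were shared, 97.1 were on average (highest of 100 simulations 138). These simulations left out the shift of whole arrays in PABPC1 and SLBP RIP. They therefore do not give the overlap to be expected of lists as long as the real ones. All pairs use the same 3 controls, which cannot be split, so part of the excess over independent lists is shared by construction. ELAVL1 and CELF1 RIP shared 1097 of the 1600 features higher in the smaller group, where independent lists would share 456. ELAVL1 RIP and the arrays labelled IGF2BP1 shared 2368 of the 5537 (independent 1578.5), and SLBP and PABPC1 RIP 18203 of the 19140 (independent 15906.6). Across features, the covariance of the fold changes of ELAVL1 and CELF1 RIP was 0.606, against 0.453 from shared controls alone. Their correlation went the other way, at 0.499 against 0.838 in the simulations. In every other pair too the covariance lay above the simulated value and the correlation below it. Without negative control replicate 3, 3285 features were higher in all 5, with quantile normalization 204, and at an adjusted p under 0.01 338.

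The deposited region lists gave, for each RBP, transcript regions on hg19 with a fold and a p, and were compared with the calls from the array values. Genes are named here from regions of features with exactly 1 gene symbol. Among those, ZNF738, a zinc-finger gene, had the largest fold for ELAVL1 in the authors' deposited table, and TMEM200A, a membrane protein gene, the largest for PABPC1. The same held for MACC1, a gene of cell migration, in the CELF1 list, for PPP1R13L, an inhibitor of p53, in the SLBP list, and for ZNRF3, a ubiquitin ligase gene of WNT signalling, in the list attached to the arrays labelled IGF2BP1. The lists held 6425 regions for ELAVL1, 6499 for PABPC1, 518 for CELF1, 4526 for SLBP and 2673 for IGF2BP1. In the authors' deposited table the folds of ZNF738, TMEM200A, MACC1, PPP1R13L and ZNRF3 were 56.4, 584, 24.2, 98.3 and 130. For CELF1 the authors' deposited table also held a region without a gene symbol and with a larger fold (28.3). ZNF738 lay on chromosome 19, 21541735 to 21562111, and TMEM200A on chromosome 6, 130686879 to 130764509, as the files give them; whether they count from 0 or 1 is not stated. The next folds among regions with 1 gene symbol in the authors' deposited table were 53.2 (PANK2) and 44.0 (RBMS3) for ELAVL1, 469 (ALDH7A1) and 440 (CCL20) for PABPC1, 19.6 (TM2D3) and 17.9 (LAPTM4A) for CELF1, 72.2 (KRTAP5-9) and 67.8 (MIRLET7BHG) for SLBP, and 65.1 (NDUFS7) and 61.2 (MOSPD3) for IGF2BP1. In the authors' deposited table the q of MACC1, TM2D3 and LAPTM4A was 0.0912, 0.103 and 0.154, so none of these CELF1 regions lay under 0.05. What the folds were divided by is not given in the sources used here.

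Every region of the RBP lists had a deposited p under 0.05, and the deposited q was under 0.05 for 83.6% of ELAVL1, 69.1% of PABPC1, 31.5% of CELF1, 55.3% of SLBP and 50.7% of IGF2BP1 regions. Of the listed features, limma called 54.9% for ELAVL1, 92.4% for PABPC1, 30.9% for CELF1, 80.7% for SLBP and 68.7% for the arrays labelled IGF2BP1 higher than in the negative control. Over all 28869 features, limma called 8230, 23992, 1600, 19140 and 5537 higher in the same order. Most features were thus higher in PABPC1 and SLBP RIP, listed or not. Listed features called lower were 191, 31, 6, 46 and 37. Between RBPs, 13919 of 20641 regions (67.4%) overlapped a region of another RBP by at least 1 base, and 7 features were in all 5 lists. Among regions above the median value of their own list, 4761 overlapped another. The list attached to the negative control sample held 17292 regions, and each of its values equalled the geometric mean of the 3 total input arrays within 0.001. The list attached to a total input sample held 7 regions, all with a deposited q of 0.579. The first of these 2 lists is named for the input and the second for the negative control. Of the first list's values only 21 lay within 0.001 of the negative control level, which argues against its attachment to that control. Which arrays gave the second list is left open. Neither was used for comparisons between RBPs.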

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

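The comparisons, the fixed gene lists, the rule for naming genes and the counts over other splits of the arrays were chosen before the data were examined; the erythroid and B-lineage marker tests, the olfactory receptor and within-batch tests and the blocked list values below were chosen only after the result was seen. Differences between RBP RIPs were singled out for 3 lists in the test of 1 RIP against the mean of the other 4. The B-cell list was called with a relative median of at least 2 either way. The small structured and small nucleolar RNA lists were taken because they were called with an estimated correlation, so that adjusted p is no separate support. Small structured RNAs lay -1.84 relative to all features in PABPC1 RIP (camera adjusted p 1.87e-16, and 0.00172 with an estimated correlation). Small nucleolar RNAs lay 0.85 above all features in SLBP RIP (adjusted p 7.25e-19, and 0.0469 with an estimated correlation), and 0.82 with the array batch as a fixed block. That blocked value argues against the batch as the whole cause, but it runs partly through the 3 arrays that stood apart. B-cell identity genes lay -2.12 relative to all features on the arrays labelled IGF2BP1 (adjusted p 5.78e-05, and 0.51 with an estimated correlation).

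HBZ, HBE1 and ALAS2 were high on the arrays labelled IGF2BP1 and negative control replicate 3. The erythroid marker median of negative control replicate 3 lay 2.05 above the highest of the 17 other arrays, and on the arrays labelled IGF2BP1 the B-cell list, fixed beforehand, lay -2.12 relative to all features. The array batch is argued against: the other 5 arrays in the batch of negative control replicate 3 had a median of 0.23, and the highest of the other 4 in the batch of the arrays labelled IGF2BP1 was 0.084. A candidate explanation is RNA of erythroid-type cells such as K562 on these 4 arrays, by a mixed or wrongly labelled sample. Binding of such mRNAs by IGF2BP1 cannot be told apart from this on its own arrays, because the lowest of them lay only 0.71 above negative control replicate 3, an array made without that antibody, and 1 array decides only for itself.

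Olfactory receptor genes, which B cells are not known to express, rose with all features in PABPC1 and SLBP RIP. Their median log2 fold change over the negative control was 1.72 in PABPC1 RIP and 1.33 in SLBP RIP. The array batch is argued against, since the median shift over total input within a batch was 2.67 for PABPC1 and 1.71 for SLBP. Brighter arrays or more labelled cDNA may explain a large part of both shifts. Binding of most expressed mRNAs by PABPC1 stays open, because respiratory chain genes shifted by 3.21 more than olfactory receptor genes, which a brighter array could also do to expressed genes.

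Histone transcripts such as H2BC14 and H3C3 were higher in SLBP RIP than in the negative control, as binding by SLBP would give. Under a fixed block for the batch the relative median of the list went from 1.73 to -0.029, so the batch may account for it. Relative to total input within the batch the list lay 0.16 above all features in SLBP RIP and 0.51 on the arrays labelled IGF2BP1. Relative to the array median, the histone level was 2.49 on that total input array and 2.33 to 2.43 on the SLBP RIP arrays. So no clear rise in SLBP RIP was seen with the batch held the same. With 1 total input array in the batch, this does not decide about binding by SLBP. Without negative control replicate 2, which had a low histone level, the list lay 0.77 above all features and its call ended, which leaves the share of that array open.

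For comparisons of 3 arrays with 3, the 10 possible splits are too few for a share under 0.05. Against the negative control the real split called 9657 features for ELAVL1 (highest other split 6715), 24208 for PABPC1, 2194 for CELF1, 19483 for SLBP and 6344 for the arrays labelled IGF2BP1 (highest other 3078, with negative control replicate 3 on their side). The other splits for PABPC1, CELF1 and SLBP gave 0 with limma, and at an unadjusted p under 0.05 at most 7199, 7527 and 7722. Against total input the real splits called 11197 for ELAVL1 (highest other 7), 24432 for PABPC1, 1784 for CELF1, 20309 for SLBP and 6906 for the arrays labelled IGF2BP1, the last 4 with 0 by limma in the other splits and at most 5759, 2407, 2649 and 2754 at an unadjusted p under 0.05. In each of these 10 comparisons 1 split, the real one, gave as many calls. Between negative control and total input 3 of 10 splits gave at least the real 1297, and the split of negative control replicates 1 and 2 with total input replicate 1 from the rest gave 10227, which points to a structure of the samples other than their groups. For each RBP against the other 12 RBP arrays pooled, 100 splits were drawn. Pooling gave other counts than the comparison with the mean of the other 4 RIPs, so the splits do not exclude chance for that comparison. The splits treat the 15 arrays as exchangeable, although all CELF1 arrays shared 1 batch and all SLBP arrays and arrays labelled IGF2BP1 another, so they leave the batch open. ELAVL1 had 194 higher features in the real split and 0 by limma in the highest other drawn for it (8399 at an unadjusted p under 0.05), and PABPC1 21025 against 13288, each with 1 split as large. Splits of the same 15 arrays drawn for other RBPs gave up to 21025, so the share for ELAVL1 depends on the draw. CELF1 had 76 (3 splits as large), SLBP 423 (3) and the arrays labelled IGF2BP1 113 (4), against up to 21025, 13288 and 11230 in splits that put PABPC1 arrays together, a structure of the samples that follows the high signal of PABPC1 RIP.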

How the results depend on the processing

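Leaving out arrays chosen for their profile, leaving out the arrays labelled IGF2BP1 and averaging PABPC1 replicates 1 and 2 were alternatives chosen after the data were seen; the others were fixed earlier. IGF2BP1 stands here for the arrays labelled IGF2BP1. Of 509 values of 26 counts, 363 lay within 1.5 times the reported count and 146 beyond. Of 1297 values of gene lists, 1057 kept direction and side of the threshold, 169 lost the call, 23 gained one and 48 reversed, and of 4064 values of named genes 3960, 100, 2 and 2. Quantile normalization gave against the negative control ELAVL1 3566 higher and 3958 lower, PABPC1 5473 higher and 5987 lower, SLBP 3141 higher and 3513 lower, IGF2BP1 3241 higher and 1869 lower, against total input PABPC1 11715, SLBP 7335, higher than the other RBPs ELAVL1 2855, PABPC1 2265, CELF1 3855, SLBP 1551, IGF2BP1 3277, lists called against the negative control 51, features higher in all 5 RIPs 204 and reversed tests for SLBP against the negative control olfactory receptor -0.24 (relative medians). Centring arrays on their medians gave against the negative control ELAVL1 2968 higher and 3829 lower, PABPC1 7351 higher and 11542 lower, SLBP 2430 higher and 6028 lower, IGF2BP1 3456 higher and 2080 lower, against total input ELAVL1 7291, SLBP 8773, higher than the other RBPs ELAVL1 3363, PABPC1 5260, CELF1 4783, SLBP 1000, IGF2BP1 4553 and reversed tests for SLBP against the negative control olfactory receptor -0.22 (relative medians). Only features above the median level, which tests fewer features, gave against the negative control ELAVL1 4386 higher, PABPC1 12156 higher, SLBP 9714 higher, against total input ELAVL1 6509, PABPC1 12500, SLBP 10515, higher than the other RBPs ELAVL1 485, PABPC1 12664, SLBP 2662, lists called against the negative control 21. Only features with 1 symbol, again fewer, gave against the negative control PABPC1 79 lower, IGF2BP1 537 lower, higher than the other RBPs ELAVL1 510, CELF1 431, SLBP 3537. Array weights gave against the negative control ELAVL1 4713 higher and 455 lower, PABPC1 90 lower, CELF1 857 higher and 128 lower, SLBP 10123 higher and 94 lower, IGF2BP1 248 lower, negative control against total input 107 higher and 504 lower, against total input ELAVL1 22695, CELF1 9675, IGF2BP1 17223, higher than the other RBPs ELAVL1 5658, CELF1 1417, SLBP 17195, IGF2BP1 3438, lists called against the negative control 71 and reversed tests for IGF2BP1 against the negative control B-cell 1.07, ELAVL1 against the negative control ribosomal protein -0.075, SLBP against the negative control olfactory receptor -0.25, PABPC1 against the negative control histone 0.63 (relative medians). Fitting only the compared groups, with fewer arrays, gave against the negative control ELAVL1 2786 higher and 366 lower, PABPC1 116 lower, CELF1 394 higher and 147 lower, SLBP 218 lower, IGF2BP1 2409 higher and 273 lower, negative control against total input 23 higher and 50 lower, against total input ELAVL1 7349, CELF1 1061, higher than the other RBPs ELAVL1 2335, CELF1 1104, SLBP 12898, IGF2BP1 2462. The array batch as a fixed block gave against the negative control ELAVL1 2055 higher and 469 lower, PABPC1 15475 higher, SLBP 7331 higher, IGF2BP1 1322 higher, negative control against total input 2052 higher, against total input ELAVL1 3351, CELF1 6049, IGF2BP1 3403, higher than the other RBPs ELAVL1 348, PABPC1 11829, SLBP 1894, IGF2BP1 418, CELF1 -0.21 in IGF2BP1 RIP against the negative control, KRT4 -0.13 in ELAVL1 RIP against the other RBPs and reversed tests for ELAVL1 against the negative control B-cell -0.41, NF-kappaB -0.16, SLBP against the negative control NF-kappaB -0.69, polyadenylated histone -0.94, histone -0.029, AU-rich -0.41, IGF2BP1 against the negative control ribosomal protein -0.49, glycolysis -1.07, mitosis -1.68, respiratory -0.70, TOP mRNA -1.26, proteasome -1.19, histone -0.26, PABPC1 against the negative control mitosis 0.52, respiratory 0.64, proteasome 0.31, ELAVL1 against the other RBPs respiratory 0.38, proteasome 0.50, IGF2BP1 against the other RBPs respiratory -0.43, CELF1 against the other RBPs CELF1 target 1.24 (relative medians). For ELAVL1 against the negative control that fixed block compares 1 array with 1, so its counts borrow the spread of other groups. The blocked comparisons of PABPC1, SLBP and IGF2BP1 with the negative control run through negative control replicates 2 and 3 and total input replicate 1. As a random block the array batch gave against the negative control SLBP 209 lower, IGF2BP1 473 lower, higher than the other RBPs CELF1 379. Within the batch of CELF1 RIP, with fewer arrays, limma gave against the negative control CELF1 159 higher and 59 lower, negative control against total input 0 higher and 0 lower (2988 features at an unadjusted p under 0.05), against total input CELF1 504. Within the batch of SLBP RIP it gave against total input IGF2BP1 11320. Negative control replicates 2 and 3 and total input replicate 1 left out gave against the negative control CELF1 3800 higher and 1391 lower, IGF2BP1 1666 lower, negative control against total input 1191 higher and 1949 lower, against total input CELF1 3234 and reversed tests for CELF1 against the negative control B-cell -0.46, NF-kappaB -0.63, ELAVL1 against the negative control B-cell -0.53, NF-kappaB -0.34 (relative medians). Those 3 arrays left out, with an estimated correlation, gave lists called against the negative control 0 and the same reversed tests. The arrays labelled IGF2BP1 left out gave higher than the other RBPs ELAVL1 634, SLBP 2843. An estimated correlation alone gave lists called against the negative control 1. The set test fry, which tests the members' own direction and not that relative to other features, gave lists called against the negative control 60 and the opposite direction for IGF2BP1 against the other RBPs T-cell, myeloid and erythroid 0.24, ELAVL1 against the negative control ribosomal protein -0.51, SLBP against the other RBPs respiratory -0.33, PABPC1 against the negative control olfactory receptor -0.69, histone 0.043, small nucleolar RNA -0.89, small structured RNA -2.23, PABPC1 against the other RBPs histone -0.72, small nucleolar RNA -0.99, small structured RNA -1.84, ELAVL1 against the other RBPs AU-rich 0.29, IGF2BP1 against the negative control small nucleolar RNA -0.25, CELF1 against the other RBPs small structured RNA 0.92 (relative medians). A stricter adjusted p of 0.01 gave features higher in all 5 RIPs 338. Negative control replicate 3 left out gave features higher in all 5 RIPs 3285. Only regions above their list's median value, fewer by construction, gave overlapping regions 4761. Leaving out 1 array at a time moved these counts beyond 1.5 times: ELAVL1 lower against the negative control 846 to 2718 (846 without negative control replicate 2, 2718 without negative control replicate 3, 881 without ELAVL1 replicate 2), PABPC1 lower against the negative control 113 to 333 (113 without negative control replicate 2, 333 without negative control replicate 3), CELF1 higher against the negative control 1079 to 4305 (4305 without negative control replicate 3), CELF1 lower against the negative control 364 to 1560 (386 without negative control replicate 2, 1560 without negative control replicate 3, 385 without CELF1 replicate 2, 364 without CELF1 replicate 3), SLBP lower against the negative control 222 to 582 (222 without negative control replicate 2, 582 without negative control replicate 3), IGF2BP1 lower against the negative control 476 to 1903 (476 without negative control replicate 2, 1903 without negative control replicate 3), negative control higher against total input 315 to 1127 (315 without negative control replicate 1, 1127 without negative control replicate 3), negative control lower against total input 698 to 1945 (1945 without negative control replicate 3), CELF1 against total input 1124 to 2218 (1178 without total input replicate 1, 1169 without CELF1 replicate 1, 1124 without CELF1 replicate 2, 1128 without CELF1 replicate 3), ELAVL1 higher than the other RBPs 625 to 1219 (625 without ELAVL1 replicate 2), CELF1 higher than the other RBPs 429 to 815 (429 without CELF1 replicate 1, 444 without CELF1 replicate 2), SLBP higher than the other RBPs 2358 to 6587 (3642 without SLBP replicate 1, 2358 without SLBP replicate 2, 3123 without SLBP replicate 3), IGF2BP1 higher than the other RBPs 813 to 1414 (813 without IGF2BP1 replicate 1, 832 without IGF2BP1 replicate 3). The B-cell list against the negative control on the arrays labelled IGF2BP1 ranged from -0.15 to 1.10, and its test reversed without negative control replicate 1. The replicate number as a replicate block gave 8644 higher and 1529 lower for ELAVL1 against the negative control and 32 lists called against it, with every count within 1.5 times and the call of 1 list lost. Same-numbered arrays do not pair: 27 of 63 pairs correlated over 0.1 (-0.358 to 0.426). The trend and robust variance model and the PABPC1 replicates averaged changed no call of a named gene or list. Other pseudocounts were not run, since the deposited values are already log2. Except where fewer features or arrays were tested, the cause was not tested. Signal near the floor limits what can be seen of dim features.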

Other observations

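CELF1 mRNA was higher than in the negative control in RIPs of other proteins and was not called in its own. Its log2 fold change was 3.64 (adjusted p 0.000174) in ELAVL1 RIP, 4.80 (adjusted p 4.82e-07) in PABPC1 RIP, 2.96 (adjusted p 0.000333) in SLBP RIP, 1.82 (adjusted p 0.0317) on the arrays labelled IGF2BP1 and 1.10 (adjusted p 0.383) in CELF1 RIP. Under a fixed block for the array batch it was 2.31 in ELAVL1 RIP (adjusted p 0.125), 0.93 in SLBP RIP (0.515) and -0.21 on the arrays labelled IGF2BP1 (0.922), so these 3 calls ended, at the highest adjusted p of their alternatives. In SLBP RIP the call also ended on centring arrays on their medians (adjusted p 0.139) and on quantile normalization (0.0545). On the arrays labelled IGF2BP1 it also ended on both (0.129 and 0.188), with a random block (0.275), with only the compared groups (0.153), with the 3 arrays that stood apart left out (0.0515), and without negative control replicate 2 (0.246) or replicates 1 (0.0977) or 3 (0.0999) of the arrays labelled IGF2BP1. The comparison of CELF1 RIP with the mean of the other 4 RBP RIPs included this gene, but its value is not given here. No test of an explanation was made in this part.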
